A study of Mus musculus with 6 samples.

How the data were processed

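mProx24, a line of proximal tubular epithelial cells from mouse kidney, was profiled on Agilent microarrays for mouse miRNAs, with 1 dye and 1 array for each of 6 conditions. Per the labels, the conditions were an untreated control, high glucose, palmitate (150 µM with 0.15% albumin for 9 h), low oxygen (1% for 12 h), the 3 stimuli together, and the 3 stimuli after 12 h of pre-treatment with rapamycin (0.4 µg/ml), an inhibitor of the mTORC1 kinase complex. The control, high glucose and palmitate cultures were kept at 20% oxygen, and each array was hybridised with labelled product of 100 ng RNA. The labels give albumin only for cultures with palmitate, so palmitate and albumin cannot be told apart. Each condition was taken from the title of its sample, and each scanner file was assigned to the sample it was deposited under.

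Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 10.7.3.1, which subtracted background and flagged outlier spots. The spot values used here are the authors' deposited intensity values on a linear scale, not normalised between arrays, with 1 array per sample and nothing pooled. The deposited table of processed values holds a linear signal per miRNA. Each of its columns was checked against the scanner files. For 1 scanner file each, it equalled the software's summed signal per miRNA divided by 1 factor, within 0.1%, for 68.7% to 73.5% of the miRNAs compared. How the authors chose that factor is not given in the sources used here; the values are on a linear scale and are not centred. The column medians equal the column floors, since most miRNAs lie at the floor, and run from 0.00341 for palmitate to 0.00475 for the control.

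For 2 samples the table and the scanner files disagreed. The table's palmitate column matched the scanner file deposited under high glucose for 70.6% of miRNAs, its high glucose column matched the scanner file deposited under palmitate for 70.9%, and each matched its own scanner file for 0%. The comparisons below follow the scanner files, and the exchange of these labels is reported beside the results it touches. The control, hypoxia, triple stimuli and rapamycin arrays matched their own columns.

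A probe's value was the mean processed intensity of its spots that were not flagged as outliers, with a median of 18 spots per probe. Each array was scaled to its 75th percentile over the 281 probes detected on all 6 arrays, floored at its lowest signal among detected probes, and moved to log2. A probe counted as detected where at least 0.5 of its spots were well above background, and a miRNA where any of its 1 to 4 probes was. The brightest probe stood for each miRNA. In 5 cases that probe was not well above background on an array on which another probe of the same miRNA was. The arrays carried 3105 probes for 1247 miRNAs, all of them mouse miRNAs. No spot was saturated, and 4.26% to 4.44% of the miRNA spots carried an outlier flag.

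With 1 array per condition, comparisons of 2 arrays have no replicate check and no p-value. A miRNA was called higher or lower where it was detected on both arrays and differed by at least 1.5-fold and by more than 2 standard errors. That error covers the spread between spots within an array only. A miRNA detected on 1 of the 2 arrays has a bound, written as at least N-fold, against the higher of its own signal and the lowest detected signal on the dimmer array. The arrays at 1% and 20% oxygen, 3 against 3, were compared with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, over the 154 miRNAs detected on all 6 arrays. The other treatments are unevenly spread over the 2 sides, with rapamycin at 1% oxygen only. They enter both the spread and the difference of that comparison. In simulated data with the residual spread of these arrays and 154 miRNAs (20 runs), that fit called 79% of planted 1.5-fold changes, 96% of 2-fold changes and 0.97% of unchanged miRNAs. Each run planted many changes at once, up to 4-fold, which makes the Benjamini-Hochberg adjustment more lenient than where few miRNAs change. A lone 1.5-fold change would be called less often, by a share that was not simulated. The rule for 2 arrays, tested on simulated data in 1 run of 164 miRNAs, called 53% of 1.5-fold changes, 100% of 2-fold changes and 0% of unchanged miRNAs. Its noise was the robust SD of palmitate minus control (0.12), the lowest of the comparisons, against 0.24 for triple stimuli minus control. The 0% holds for that noise only. The simulated unchanged arrays below used the same noise.

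The 19 miRNA lists, the comparisons and most alternatives were fixed before the data were examined. The lists were low-oxygen responsive miRNAs, the miR-200, let-7, miR-29, miR-17/92 and miR-148/152 families, proximal tubule and kidney epithelium, renal fibrosis and diabetic kidney, p53 and apoptosis, mTOR targeting, lipid and glucose metabolism, inflammation and NF-kB, the Dlk1-Dio3 and Sfmbt2 clusters, high-numbered miRBase entries, and markers of blood, endothelial, fibroblast and smooth muscle, and muscle, neuron and hepatocyte cells. A list's median difference is given with its percentile among 10000 random lists of the same size matched on mean signal, as a description of these arrays. Named miRNAs were the 8 highest and 8 lowest among those called whose probes detected on both arrays shared a sign, up to 3 per direction with a bound of at least 1.5-fold, and each list's extreme members. For oxygen, the 5 largest differences were named if fewer than 5 miRNAs passed. miR-210-3p, miR-21a-5p and the miR-148/152 family were always considered, the last because it is known as a subject of the study, so its choice was not independent of these arrays. Alternatives covered the scaling (all probes, median, quantile, none), normexp background correction with an offset of 50, the mean of all probes, the scanner software's summed signal, the detection filter, the deposited value table, odd- or even-numbered spots, and, for oxygen, a variance trend and each array left out. Scaling to spike-in RNAs, both ways of exchanging the labels, and all alternatives for triple stimuli against hypoxia, rapamycin against the control and the sum of single stimuli were added after the data were seen. Control spots were left out of all comparisons.

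All arrays lay on 1 slide and were scanned together. The 20% oxygen arrays filled the first row of the slide and the 1% oxygen arrays the second, so oxygen and slide row cannot be told apart. Positions are those the scanner files list for a probe, given only where they fall inside a miRNA gene of the GRCm38.p6 annotation. The file headers name an older build, so other listed positions were not used here.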

Results

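Agilent miRNA arrays were read from mProx24 mouse proximal tubular cells under 6 conditions, with 1 array each: control, high glucose, palmitate, hypoxia (1% oxygen), the 3 stimuli together, and the 3 stimuli with rapamycin. Of 1247 miRNAs on the array, 198 were detected on at least 1 array. The number detected was 164 in the control, 189 in high glucose, 162 in palmitate, 172 in hypoxia, 185 in triple stimuli, and it was highest in triple stimuli plus rapamycin. Between 11.4% and 13.3% of miRNA spots were well above background, and the median spread between spots of a detected probe was 6.57% to 10.4%. The number of arrays limits the precision of every comparison.

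All 9 let-7 family members, all 3 miR-29 members and 10 of 12 miR-17/92 members were detected on all 6 arrays. Of the 12 proximal tubule and kidney epithelium miRNAs, 7 were detected, namely miR-10a-5p, miR-10b-5p and miR-30a-5p to miR-30e-5p. Not detected on any array were miR-192-5p, miR-194-5p, miR-215-5p, miR-204-5p and miR-146b-5p. None of the 7 miR-200 family miRNAs, which are typical of epithelia, was detected on any array, nor were the 6 blood, 2 endothelial or 5 fibroblast and smooth muscle markers. Of the 6 muscle, neuron and hepatocyte markers 1 was detected, the muscle miRNA miR-206-3p, which was present on all 6 arrays. The Dlk1-Dio3 cluster was represented by miR-494-3p alone among 27 members on the array, and the Sfmbt2 cluster by 5 of 61.

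Of the family of miR-148 and miR-152, which is among the fixed lists, none met the detection rule on any array. The scanner software's own rule called miR-148b-3p detected on 4 of 6 arrays, with summed signals of 4.27 ± 1.87 (software error) in the control, 5.90 ± 1.97 in high glucose, 6.15 ± 1.96 in palmitate, 5.66 ± 1.90 in hypoxia, 4.61 ± 1.89 in triple stimuli and 6.25 ± 1.86 in triple stimuli plus rapamycin. These values of miR-148b-3p differed by less than the sum of the errors of any 2 arrays. By the same rule miR-152-3p was called on 5 arrays and miR-148a-3p on 0.

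Low oxygen was the question of the hypoxia array. miR-210-3p, the miRNA most widely known to be induced by hypoxia-inducible factor, was higher in hypoxia than in the control by at least 10.5-fold (log2 3.40). It was not detected in the control, at a signal of 24.7, and stood at 260 in hypoxia. Its bound against the control was 8.88-fold in triple stimuli and 8.34-fold in triple stimuli plus rapamycin, and both of its probes were detected on all 3 arrays at 1% oxygen. The probe of miR-210-3p maps to chromosome 7, 141221455 to 141221470, inside Mir210.

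**Figure D1:**
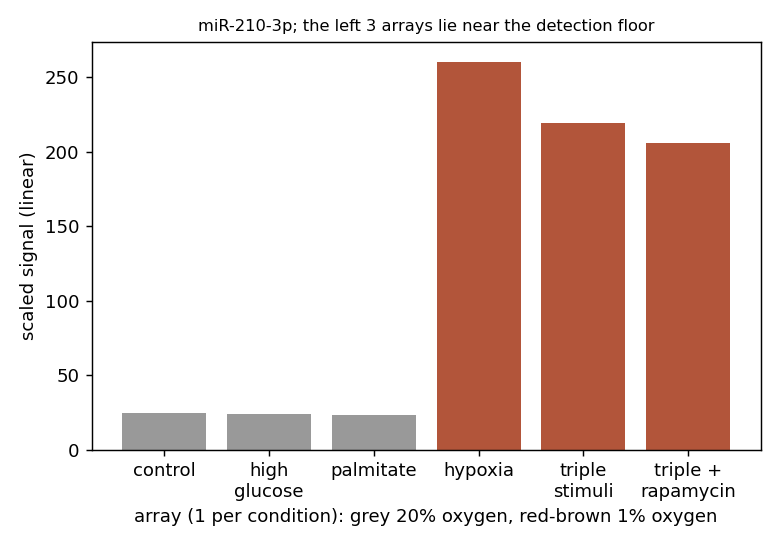
Scaled linear signal of miR-210-3p on each of the 6 arrays, 1 bar per array, grey for 20% and red-brown for 1% oxygen. Hypoxia read 260 and triple stimuli 219, and the 3 arrays at 20% oxygen read 24.7, 24.1 and 23.2, near the lowest detected signal.

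Apart from miR-210-3p, few miRNAs separated hypoxia from the control. Of 162 miRNAs detected on both arrays, 0 were higher and 3 lower: miR-714 (log2 -0.80, spot SE 0.17), miR-5107-5p (-0.69, spot SE 0.07) and miR-709 (-0.63, spot SE 0.01). miR-21a-5p, raised in many forms of kidney injury, differed by 0.14 (spot SE 0.03), below the 1.5-fold limit. The low-oxygen list had 13 members detected on both arrays, 0 of them past 1.5-fold, from -0.23 for miR-155-5p to 0.41 for miR-322-5p. Its median of -0.07 lay at percentile 83.9 of matched lists, was -0.05 with the bound of miR-210-3p included, and turned positive with no scaling (0.11), spike-in scaling (0.06) or the summed signal (0.09). Among other lists, the highest and lowest members were miR-29c-3p (0.31) and miR-29b-3p (-0.05) of the miR-29 family, miR-19a-3p (0.19) and miR-92a-3p (-0.27) of the miR-17/92 family, and miR-10a-5p (0.14) and miR-30e-5p (-0.25) of the kidney list. A further 10 miRNAs were detected in hypoxia alone and 2 in the control alone; of these, miR-210-3p was the 1 with a bound of 1.5-fold or more. The 3 lower calls depended on the processing, with 0 under normexp or the summed signal and 1 under quantile or spike-in scaling; no scaling gave 2 higher and 1 lower and moved the median over all miRNAs from -0.11 to 0.08.

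Grouping the arrays by oxygen asked what 1% oxygen did across treatments. Only miRNAs detected on all 6 arrays entered the test, so miR-210-3p stood outside it; its bound between the 3 arrays at 1% and the 3 at 20% was at least 9.47-fold, from mean log2 7.83 ± 0.18 (SD, n = 3) against 4.59 at the limit. It was detected on 1 of the 3 arrays at 20%. Of the miRNAs tested, 0 passed an adjusted p of 0.05 in limma, and 7 had an unadjusted p under 0.05 where 7.7 were due by chance. The 5 largest differences, none past the threshold, were miR-712-5p (-0.46, SE 0.17, adjusted p = 0.747), miR-714 (-0.44), miR-5126 (0.39), miR-5097 (0.38) and miR-2861 (0.37). The lowest adjusted p was 0.408, for miR-350-3p (0.37, SE 0.08). miRNAs whose 2 oxygen groups did not overlap made up 11%, against 10% by chance. For the low-oxygen list 0 of 13 members passed when adjusted over the list alone, and 0 over all miRNAs tested; in the other lists 0 passed either way. When miRNAs detected on at least 1 array were tested, miR-210-3p was the 1 that passed, with adjusted p = 8.99e-06. That p-value rests on values at or near the floor on the 20% oxygen arrays, so their spread is set in part by the floor. Slide row was the same split as oxygen, and the other treatments were unevenly spread over the 2 sides.

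The array labelled high glucose differed most from the control of the 3 single stimuli in its count of higher miRNAs. Of 162 miRNAs detected on both arrays, 11 were higher and 0 lower. The highest were miR-5126 (5.79-fold, log2 2.53, spot SE 0.02), miR-2861 (5.13-fold) and miR-3102-5p (4.34-fold). They were followed by miR-6538 (2.74-fold), miR-6378 (2.69-fold), miR-211-3p (2.48-fold), miR-3960 (2.07-fold) and miR-2137 (1.89-fold). miR-2861 and miR-3960 are neighbours on chromosome 2, where their probes map to 32712869 to 32712876 and 32712956 to 32712965. A further 27 miRNAs were detected on this array and not in the control, against 2 the other way. The control array was dimmer before scaling, with a 75th percentile of 295 against 360 here. Of the 27, 7 were at least 1.5-fold higher, led by miR-149-3p (at least 3.51-fold), miR-135a-1-3p (at least 3.35-fold) and miR-680 (at least 3.17-fold).

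Of these 11 miRNAs, 10 belonged to the list of high-numbered miRBase entries, which had 48 members detected on both arrays; its median of 0.02 lay at percentile 99.8 of matched lists (-0.05 with scaling over all probes, -0.09 with scaling to the median, -0.02 with quantile normalisation), from -0.32 for miR-5097 to 2.53 for miR-5126. The miRNAs with known roles in kidney cells moved little: miR-21a-5p differed by 0.25 (spot SE 0.03), and no member of the let-7, miR-29, miR-17/92, fibrosis, p53, mTOR, metabolism or inflammation lists passed 1.5-fold. The miR-29 family, which represses collagens, ran from 0.04 for miR-29b-3p to 0.38 for miR-29c-3p. The kidney list ran from -0.31 for miR-30a-5p to -0.0038 for miR-30b-5p, with its median of -0.15 at percentile 6; the median turned to 0.13 with no scaling and 0.03 with spike-in scaling. miR-181b-5p was lowest of the low-oxygen list at -0.39 and miR-370-3p lowest of the metabolism list at -0.29. Scaling to the median of detected probes gave 9 higher and 2 lower, quantile normalisation 8 and 2, and no scaling 20 and 0. The median over all miRNAs, -0.05 here, was 0.23 with no scaling. The deposited value table assigns this array to palmitate; by its labels the 11 higher miRNAs belong to palmitate, and high glucose had 0 higher and 4 lower.

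The array labelled palmitate, a saturated fatty acid used to model lipid overload, had 0 higher and 4 lower among the miRNAs detected on both arrays. The lower ones were miR-6366 (log2 -0.81, spot SE 0.02), miR-5097 (-0.79), miR-212-3p (-0.76, spot SE 0.08) and miR-5100 (-0.70). miR-212-3p, which shares a primary transcript with miR-132 and is induced by CREB, was the 1 of 4 members of the inflammation list past 1.5-fold; miR-155-5p of that list differed by 0.06. miR-21a-5p differed by -0.08 (spot SE 0.02). In the mTOR list miR-7a-5p was highest (0.28) and miR-222-3p lowest (-0.11), and in the miR-17/92 family miR-19a-3p was highest (0.13) and miR-17-5p lowest (-0.17). The high-numbered list had a median of -0.0079 (0.18 with scaling over all probes) at percentile 95.7, from -0.81 for miR-6366 to 0.53 for miR-1897-5p. Detected on this array alone were 7 miRNAs and in the control alone 9, none with a bound of 1.5-fold. Scaling over all probes gave 3 higher and 2 lower, quantile normalisation 2 and 2, scaling to the median 2 and 4, and no scaling 2 and 4; the first of these moved the median over all miRNAs from -0.03 to 0.15. By the value table's labels these values belong to high glucose.

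Triple stimuli combined high glucose, palmitate and 1% oxygen. Against the control, 9 of 161 miRNAs detected on both arrays were higher and 0 lower. The highest were miR-5126 (2.62-fold, log2 1.39, spot SE 0.02), miR-2861 (2.48-fold), miR-3102-5p (2.14-fold) and miR-6538 (1.95-fold), followed by miR-211-3p (1.66-fold), miR-3960 (1.61-fold), miR-3096a-5p (1.60-fold) and miR-1897-5p (1.58-fold). miR-210-3p, miR-149-3p (at least 2.08-fold) and miR-135a-1-3p (at least 1.91-fold) led the 24 miRNAs detected in triple stimuli alone, against 3 in the control alone. Of the 9 higher miRNAs, 8 were also among the 11 of the array labelled high glucose. Both counts use the same control array, and simulated unchanged arrays gave 0 calls in all, so there was no chance value for this overlap.

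The high-numbered list had 8 of 48 members higher with triple stimuli, 0 lower and a median of 0.21, above all matched lists (percentile 100) and positive under every scaling tried. miR-21a-5p differed by 0.28 (spot SE 0.03), the highest of the low-oxygen list among members detected on both arrays, whose lowest was miR-181b-5p (-0.44). The kidney list, with 0 of 7 members past 1.5-fold, had a median of -0.15 at percentile 3.81, from -0.33 for miR-30e-5p to 0.04 for miR-10a-5p; no scaling turned it to 0.08 and spike-in scaling to 0.03. The let-7 family ran from -0.23 for let-7b-5p to 0.10 for miR-98-5p. Scaling over all probes gave 5 higher and 3 lower, the median 4 and 3, and quantile normalisation 5 and 3. With no scaling 20 were higher, with spike-in scaling 17, and 0 were lower under both. The median over all miRNAs, 0.01 here, ran from -0.16 with median scaling to 0.24 with no scaling.

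**Figure D2:**
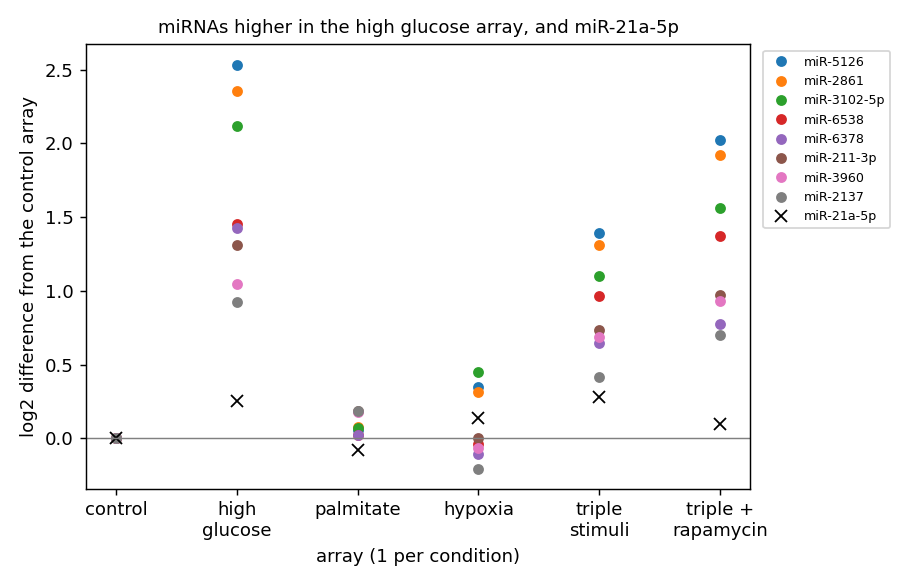
Log2 difference from the control array for the 8 highest miRNAs of the array labelled high glucose (coloured points) and for miR-21a-5p (crosses), 1 array per condition. miR-5126 stood at 2.53 in high glucose, 1.39 in triple stimuli and 2.02 in triple stimuli plus rapamycin, against 0.06 in palmitate and 0.34 in hypoxia.

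Against hypoxia, which shares the low oxygen, triple stimuli had 15 higher and 0 lower of 171 miRNAs. miR-5126 (2.07-fold), miR-6538 (2.01-fold), miR-2861 (1.99-fold), miR-3096a-5p (1.73-fold) and miR-3960 (1.69-fold) led, followed by miR-6378 (1.68-fold), miR-211-3p (1.66-fold) and miR-3096b-5p (1.64-fold). miR-149-3p was at least 2.14-fold and miR-680 at least 1.52-fold higher. miR-210-3p was detected on both arrays and differed by -0.25 (spot SE 0.04). The high-numbered list had 13 of 51 members higher. The count was 4 with median scaling, which moved the median over all miRNAs from 0.10 to -0.10, and 3 with normexp.

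Set against the sum of the 3 single stimuli, the triple response was smaller for the miRNAs that led it. Over the miRNAs detected on all 6 arrays the slope of triple minus control on the sum was 0.41, with Pearson's r of 0.87 across miRNAs, which are not independent replicates. Unchanged arrays sharing the control gave a simulated r of 0.61 and a covariance of 0.022, against an observed covariance of 0.16. The simulated covariance grows with the noise, which was taken from the comparison with the lowest spread. The size of the gap therefore depends on that choice. miR-5126 read 1.39 where the sum was 2.94, miR-3102-5p 1.10 against 2.64, and miR-2861 1.31 against 2.74. The array labelled high glucose alone already read above triple stimuli for them, at 2.53, 2.12 and 2.36. They were also the highest miRNAs on that array, so the shortfall cannot be told from that array alone reading high. The median departure from the sum was 0.20, and the simulated array noise alone gives departures an SD of 0.24. Noise around that median can therefore reach 1.5-fold above the sum. In all, 7 miRNAs lay at least 1.5-fold below the sum and 13 above it. That balance turned with the scaling, to 11 below and 7 above with scaling over all probes and to 14 below and 5 above with no scaling. Those above were led by miR-5097 (0.12 against -0.92), miR-212-3p (-0.10 against -1.13) and miR-714 (-0.13 against -1.13). Exchange of the high glucose and palmitate labels leaves the sum as it is.

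Rapamycin was added to the triple stimuli to ask what depended on mTORC1. Of 184 miRNAs detected on both arrays, 4 were higher with rapamycin and 3 lower. miR-290-5p (log2 0.66, spot SE 0.13), miR-5126 (0.63, spot SE 0.01), miR-2861 (0.61) and miR-135a-1-3p (0.59) were higher. miR-712-5p (-0.68), a miRNA-sized product of the ribosomal RNA precursor, miR-5100 (-0.66) and miR-19a-3p (-0.60, spot SE 0.05) were lower. miR-19a-3p, of the miR-17/92 cluster that MYC drives, was the 1 of 10 members of its family past 1.5-fold; miR-93-5p differed by 0.04. miR-210-3p differed by -0.09 (spot SE 0.03) and miR-21a-5p by -0.18 (spot SE 0.02).

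Other lists showed no member past 1.5-fold with rapamycin except the high-numbered entries, with 2 higher, 1 lower and 53 neither. In the mTOR list miR-99a-5p was highest (0.10) and miR-7a-5p lowest (-0.29), and the list's median of -0.11 lay at percentile 32.3, turning to 0.12 with scaling over all probes and 0.03 with no scaling. miR-212-3p was lowest of the inflammation list at -0.45 and miR-29b-3p lowest of the miR-29 family at -0.47. Detection was gained by 10 miRNAs with rapamycin and lost by 1, none with a bound of 1.5-fold. Scaling over all probes gave 9 higher and 0 lower, no scaling 6 and 0, the median 4 and 2, quantile normalisation 4 and 2, and spike-in scaling 4 and 1, so the lower calls rested on the scaling. Of the 4 higher calls, normexp kept 1, and the mean of all probes, even-numbered spots and detection on all 6 arrays kept 2 each. The median over all miRNAs, -0.07 here, was 0.16 with scaling over all probes.

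No miRNA passed 1.5-fold in opposite directions with the stimuli and with rapamycin. Of 161 miRNAs tested in both, 0 of the 9 higher with triple stimuli were lower with rapamycin. None was called lower with triple stimuli, so the 0 that were lower and then higher followed from that alone. Below the limit in the first step, miR-19a-3p (0.42, then -0.60) and miR-5100 (0.29, then -0.66) went opposite ways; these 2 were singled out after their values were seen. The simulation of unchanged arrays made no call in either direction, so it gave no chance value for these counts. miR-5126 and miR-2861 were higher in both steps. Across the miRNAs detected on all 6 arrays the differences for triple stimuli and for rapamycin had a Pearson's r of 0.41 and a Spearman's rho of 0.0059, where a shared triple array alone gave a simulated r of -0.50. The covariance was 0.023 against a simulated -0.0073. The size of the simulated value, but not its sign, depends on the low noise that was set. In the deposited value table, which keeps dimmer miRNAs, miR-185-5p (-1.18, then 0.75) and miR-1947-3p (-1.21, then 0.92) were lower and then higher and miR-450a-2-3p (0.91, then -1.27) higher and then lower; these were named after their values were seen. Of these, miR-185-5p was detected on all 6 arrays and read only -0.31 and then 0.07 in the scanner values used here, with no call in either step.

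Triple stimuli plus rapamycin had 12 higher and 3 lower of 164 miRNAs against the control. miR-5126 (4.06-fold), miR-2861 (3.79-fold), miR-3102-5p (2.95-fold), miR-6538 (2.58-fold) and miR-3096a-5p (1.99-fold) were highest, followed by miR-211-3p (1.96-fold), miR-3960 (1.90-fold) and miR-1897-5p (1.83-fold). miR-712-5p (-0.89), miR-714 (-0.71) and miR-99b-3p (-0.68) were lower. miR-149-3p was at least 2.80-fold and miR-135a-1-3p at least 2.88-fold higher. The array shared 9 of its higher miRNAs with the array labelled high glucose, through the same control array. The count of lower calls, 3 here, became 0 with no scaling (19 higher), 11 with median scaling (10 higher), 7 with quantile normalisation (10 higher) and 1 with spike-in scaling (16 higher). Median scaling and quantile normalisation kept all 3 lower miRNAs. Normexp, the mean of all probes and the summed signal kept 0 of the 3. The median over all miRNAs, -0.11 here, was 0.26 with no scaling.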

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

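Counts were recomputed under the alternatives, most of which changed 1 processing choice at a time. Odd- or even-numbered spots and detection on all 6 arrays did not cover every count. The value table differed in several choices at once: the signal per miRNA, the scaling and the miRNAs compared. For hypoxia against the control it compared 209 miRNAs, against 162 here. Spike-in scaling, the exchanged labels and all alternatives for the additivity, triple against hypoxia and rapamycin against control counts were chosen after seeing the data. The 1% against 20% oxygen counts stayed 0 with a variance trend, and the leave-one-out fits gave 0 to 0 in both directions, but 1 miRNA was higher with miRNAs detected on at least 1 array and 1 with the value table, miR-210-3p each time. Of the 11 miRNAs higher on the array labelled high glucose, 8 to 11 were kept under every alternative but the value table as deposited, which kept 0, and the exchanged labels. In the following, pairs are higher and lower. Scaling over all probes gave palmitate 3 and 2, triple stimuli 5 and 3, rapamycin against triple stimuli 9 and 0, high glucose 1 lower, triple against hypoxia 7 higher, and additivity 7 above and 11 below. Scaling to the median of detected probes gave palmitate 2 higher, high glucose 2 lower, triple stimuli 4 and 3, triple against hypoxia 4 higher, and rapamycin against control 11 lower. Quantile normalization gave palmitate 2 and 2, high glucose 2 lower, hypoxia 1 lower, triple stimuli 5 and 3, triple against hypoxia 5 higher, and rapamycin against control 7 lower. No scaling gave high glucose 20 higher, palmitate 2 higher, hypoxia 2 and 1, triple stimuli 20 higher, rapamycin against triple stimuli 0 lower, rapamycin against control 19 and 0, and additivity 5 above and 14 below. Spike-in scaling gave triple stimuli 17 higher, hypoxia 1 lower, rapamycin against triple stimuli 1 lower and rapamycin against control 1 lower. The normexp background gave hypoxia 0 lower, triple stimuli 4 higher, rapamycin against triple stimuli 1 and 1, rapamycin against control 5 and 0, triple against hypoxia 3 higher, and additivity 8 above and 3 below. The summed signal (gTotalGeneSignal) gave hypoxia 2 and 0, palmitate 3 higher, rapamycin against control 0 lower, and additivity 6 above and 4 below. The mean of all probes gave hypoxia 1 and 1, rapamycin against triple stimuli 2 higher and rapamycin against control 1 lower. The last of these was not among the 3 lower miRNAs of the main processing. Detection on all 6 arrays gave rapamycin against triple stimuli 2 higher. Odd-numbered spots gave triple stimuli 1 lower; even-numbered spots gave palmitate 1 higher, high glucose 1 lower and rapamycin against triple stimuli 2 higher. The value table gave high glucose 5 and 10, palmitate 21 and 8, hypoxia 9 and 6, triple stimuli 18 and 7, rapamycin against triple stimuli 10 higher, rapamycin against control 21 and 11, triple against hypoxia 3 lower, additivity 25 above and 14 below, 2 miRNAs lower with triple stimuli and higher with rapamycin, and 1 the other way. With its 2 columns exchanged, high glucose had 21 and 8 and palmitate 5 and 10, and its other counts were as before, with 1 miRNA for oxygen. With the 2 labels exchanged between scanner files, high glucose had 0 and 4 and palmitate 11 and 0, by construction. Among the 61 named differences, the 1 that changed sign was miR-149-3p on the array labelled high glucose, -0.23 in the value table as deposited. Several list medians and medians over all miRNAs also turned sign, as given above. Of 61 named differences, 51 kept their call with scaling over all probes, 51 with the median, 48 with quantile normalization and 29 with normexp; none of the others turned sign. Apart from the exchanged labels, the cause was not tested. Signal over background limits the comparisons to the 11.4% to 13.3% of spots well above background.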

Other observations

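Of the tests below, the 8-miRNA set, the fit of 3 arrays against 3, the tests of slide row and column, the test of exchanged labels, and the test of slide row for miR-210-3p were chosen only after the result was seen. The tests of scaling, GC content, splits and low oxygen were written before their values were computed.

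A set of 8 miRNAs was higher than in the control on the arrays labelled high glucose, triple stimuli and triple stimuli plus rapamycin: miR-5126, miR-2861, miR-3102-5p, miR-6538, miR-6378, miR-211-3p, miR-3960 and miR-1897-5p. Their median was 1.44 in high glucose, 0.85 in triple stimuli and 1.17 with rapamycin, against 0.07 in palmitate and -0.02 in hypoxia, though miR-1897-5p read 0.53 in palmitate, and miR-3102-5p 0.45, miR-5126 0.34 and miR-2861 0.31 in hypoxia. By the scanner files these 3 arrays share high glucose, and by the value table they share palmitate with its albumin. The set was chosen for being higher on these arrays, so the limma fit of the 3 arrays against the other 3 is no independent evidence: 13 miRNAs were higher and 2 lower at adjusted p under 0.05, among them 7 of the 8. Another 6 probes of the set had a median of 1.39, and odd- and even-numbered spots gave 1.13 and 1.11. These measure the same chosen miRNAs on the same arrays, so they are no independent evidence either.

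For this set a shared stimulus was weighed against technical causes. The lowest median over 5 scalings was 0.96, past the 1.5-fold limit, so scaling did not account for it. The median of triple plus rapamycin minus palmitate, which share a slide column, was 1.07, and that of triple stimuli minus hypoxia, which share a row, was 0.75, which neither a column nor a row effect alone would give. Members had a median of 84.3% GC, and GC correlated with the pattern over the miRNAs detected on all 6 arrays (Spearman's rho 0.32, and 0.21 without members). The 3 other miRNAs at or above that median GC (miR-5105, miR-712-5p and miR-714) had a median of -0.0353 and reached 0.06 at most, against 0.61 for the lowest member. They were what remained once the members were taken out, with detection on all 6 arrays required. That requirement dropped miR-149-3p, whose probe is also rich in G and C. Its bounds against the control were log2 1.81 in high glucose, 1.06 in triple stimuli and 1.49 with rapamycin. The 3 remaining miRNAs therefore cannot decide on GC content alone. The same 3 arrays were brighter, with scale factors of 1.02 to 1.13 against 0.873 to 0.991 and at least 185 miRNAs detected against at most 172. A difference in RNA or labelling that acts on these probes beyond scaling therefore stays open. So do GC content and a shared stimulus, with the labels of 2 arrays in doubt.

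Of 10 ways to split the 6 arrays into 3 and 3, the split along which the set was chosen called 15 miRNAs and the highest other called 0; 10 splits are too few for a share under 0.05. The oxygen split called 0, and the highest other called 15, which is the same split of high glucose, triple stimuli and rapamycin from the rest; 10 splits are again too few for a share under 0.05. Since the set was chosen by that split, its 15 calls are no independent evidence of a structure of the samples.

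For the disagreement between the value table and the scanner files, the lower of the 2 crosswise matches was 70.6%. An exchange of the high glucose and palmitate labels in 1 of the 2 sources would give this. The match is the observation that raised the disagreement, so it is no separate test of an exchange. Which source holds the right labels stays open, and with it whether the 8 miRNAs go with glucose or with palmitate.

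miR-210-3p was weighed between low oxygen and slide row, which are the same split of the arrays. The lowest 1% array exceeded the mean of the 20% arrays by 3.1, which is in line with induction by low oxygen. The largest difference between rows among the miRNAs detected on all 6 arrays was 0.46, so none of these miRNAs differed by as much. Scaling each array removes a shift shared by all miRNAs, so this value cannot decide on such a shift. A row effect on the probes of miR-210-3p alone cannot be told apart from low oxygen.

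In control spots detected on the arrays, 10 names in all, the ratio to the control array ran from 0.751 to 1.22. The highest was that of the bright corner spots in hypoxia, and without these spots the highest was 1.13, for mr_1 in high glucose.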
